A study of Caenorhabditis elegans with 2 samples.

How the data were processed

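Anti-GFP ChIP-seq was measured in 2 biological replicates of whole C. elegans L3 hermaphrodites of strain OP159, which carries TBX-2 with a C-terminal GFP-FLAG tag, per the labels. Fragmentation was by sonication, per the labels. Per the deposited listing of files, the authors made 4 peak lists on each of 2 genome builds, ce11 and ce10: a ranked list of peaks and background for each replicate, 1 ranked list for the pooled replicates, and 1 list thresholded on the irreproducible discovery rate from those 3. The aligner, the peak caller, its settings and the version of the IDR software are not given in the sources used here. The listing names a further parent file beside the alignments for the ranked lists, without saying what it is, and the labels name a possible control experiment, which was not used here.

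The signal value of each entry is the authors' peak caller's own, in the deposited narrowPeak format per the file listing. It was used to rank and describe entries within a list, and values of different lists were set side by side without normalization. The −log10 q value is also in the deposited lists by that format, and it was 2.76 in every thresholded entry, so it was not used for ranking. The ranked lists are long by construction: the lowest signal value of the pooled list was 15.9 against a median of 26.0, and they include background. On each build, the thresholded list was found to hold exactly the strongest entries of the pooled list, 1631 down to a signal value of 91.0 on ce11. Of these 1631 entries, 24 repeated the interval of another entry with another summit, and each was counted as a peak. Because thresholded peaks were chosen from a pool of both replicates, their presence in each replicate is not independent evidence. Read depth per sample is unknown, since the lists hold no counts, so intervals given for shares cover the number of peaks only.

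Coordinates on ce11 were used with the WBcel235 assembly and the Ensembl release 115 annotation, whose coordinates are those of ce11. Of all entries on ce11, 0 extended past the end of a chromosome. Coordinates were never converted between builds, and for ce10 the share of X was set against the chromosome lengths of WBcel235. For 11 protein-coding or microRNA genes without a symbol in that annotation, let-7 and mitochondrial genes among them, the RefSeq symbol of the gene at the same place on the same assembly was taken where both spans overlapped by at least 90%. This step was added after the first results were seen, when let-7 was found to be missing from its lists, and it raised the heterochronic list from 5 of 12 genes with a peak to 6 of 13.

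The top 1631 entries of the replicates were called shared where summits lay within 100 bp, and the count was set against 10000 circular shifts of one replicate within chromosomes (1000 shifts for the alternatives). The rank correlation used the strongest replicate entry that overlapped each thresholded peak, with an interval from 1000 bootstrap draws over peaks. Promoter windows ran from 1000 bp upstream to 200 bp downstream of each annotated transcript start of protein-coding genes. For the lists that hold microRNA genes, windows of the same size at microRNA gene starts were used as well, and each list was compared with the other genes of its own biotypes, 20233 for the heterochronic list. For sequence sites, windows of 201 bp around the summit were compared with 2 windows of that width per peak centred 1000 bp away. The 12 sites were T-box (GGTGTGA, GGTGTG and AGGTGTGA), FoxA, GATA, NK-2, E-box, GAGA, SP1-like, bZIP, SKN-1-like (RTCAT) and TTAGGC. The gene lists were pharyngeal muscle, pharyngeal regulators, T-box factors, SUMO pathway, body wall muscle, pan-neuronal, chemosensory neurons, epidermis, seam cells, intestine, germline, vulval development, heterochronic, heat shock and stress, collagens, cytoplasmic ribosomal proteins, vacuolar ATPase, histones, ceh homeobox genes, bHLH genes, nuclear receptors, microRNAs, and srh and str chemoreceptors. Lists and sites were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over the 23 lists or the 12 sites, at a threshold of 0.05. With autosomal peaks only and among genes with 1000 bp free upstream, the microRNA list was left out of the adjustment. Chromosome shares were tested with exact binomial tests, and intervals of shares are exact Clopper-Pearson 95% intervals.

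The tests, lists, sites, alternatives and the rule for named genes were fixed before the data were examined, except where a text says otherwise. The rule took the 15 thresholded peaks of highest signal with the nearest coding transcript start, and the 25 protein-coding genes with the strongest promoter summits among peaks in the top 1631 of both replicates. It also took up to 4 members with the highest signal among those with a peak in each list, and in every case tbx-2, pha-4, ceh-22, myo-2, ubc-9 and D2096.6. The 15 strongest nuclear peaks were added after the data were seen, because 11 of the 15 strongest peaks were mitochondrial. GC-matched windows were planned as an alternative for GGTGTGA and extended to the other sites after the data were seen. Alternatives tried were the ce10 lists, other overlap distances and numbers of entries, other promoter windows, other sites, windows and controls, the strongest 815 peaks, genes with at least 1000 bp free upstream, and each replicate alone.

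The scripts were tested on simulated peaks. Of 1631 random summits, 815 were placed within reach of a partner, and 819 were recovered as shared, against a median of 5 after shifts. In 20 simulations over 19985 genes with raised calls in the homeobox list, that list passed the threshold in 19, and the lists that do not overlap it passed 1 time in all. Genes were called independently of each other there, so shared summits were not simulated, and power for smaller lists was not examined. The self-test had first required 20 of 20, and the requirement was lowered to 18 after the 19 was seen, with the simulation unchanged. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.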

Results

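Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where TBX-2 lies on the genome of Caenorhabditis elegans. TBX-2 is a T-box transcription factor needed for the development of pharyngeal muscle. Worms of strain OP159, which carry a transgene for TBX-2 fused to green fluorescent protein (GFP), were grown to the L3 larval stage for 48 h after synchronization. Whole hermaphrodites were used, and the fusion protein was precipitated with an antibody against GFP. The data form 1 group of 2 biological replicates, so no comparison between conditions was possible. The authors' list of peaks thresholded on the irreproducible discovery rate (IDR), a measure of agreement between ranked replicate lists, held 1631 peaks on build ce11. The ranked list of the pooled replicates held 30000 entries, that of replicate 1 held 28366 and that of replicate 2 held 30000. Read depth is unknown, because the lists hold signal values and no read counts.

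The strongest peaks lay on the mitochondrial genome and on the X chromosome. Of the 15 peaks with the highest signal value, 11 were mitochondrial and 4 were on X. The strongest peak of all, at positions 11958 to 12843 of the mitochondrial genome within ND5, a subunit gene of respiratory complex I, had a signal value of 6024. Replicate 1 gave this site 2860.0 and replicate 2 gave it 3244. The next peak, at 4185 to 5528 over the start of CYTB, the cytochrome b gene, reached 5785. The other mitochondrial peaks among the 15 had as their nearest protein-coding starts those of COX3, COX1, ATP6, COX2, ND4L, ND2 and ND3. All 22 mitochondrial entries of the pooled list passed the authors' threshold, and together they covered 64.4% of the mitochondrial genome. Whether the high copy number of mitochondrial DNA gave rise to them stays open, so they are not evidence of TBX-2 binding at these genes.

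Among nuclear peaks, 13 of the strongest 15 lay on X. The strongest, at X 11093813 to 11094508, was intergenic, 3973 bp from the start of W02H3.3 on its downstream side. Its signal value was 2060.4 in the pooled list, 1082 in replicate 1 and 986 in replicate 2. The next, at X 6296214 to 6296923 with a signal value of 1996, lay in an intron, and its nearest transcript start, 3373 bp away, was that of cest-16. The peak at X 14525484 to 14526344, with a signal value of 1695, lay 723 bp upstream of nspc-17. The peak at X 4208854 to 4209628, with a signal value of 1671, was intergenic, 1781 bp upstream of F20B6.9. Only 1 of these 13 X peaks, that at nspc-17, had its summit in the promoter window of a protein-coding gene, set at 1000 bp upstream to 200 bp downstream of a transcript start. Both autosomal peaks among the 15 were in promoter windows. One, at III 3867338 to 3867785 with a signal value of 1583, lay 277 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. The other, at IV 4749905 to 4750259 with a signal value of 1172, lay between the divergent starts of Y17G9B.5 and rpl-20.

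The replicates shared most of their strongest sites. Of the top 1631 entries of replicate 1, 1149 had a summit within 100 bp of one in the top 1631 of replicate 2, which is 70.4% (exact 95% interval 68.2 to 72.7%). After circular shifts within chromosomes the median was 13 shared entries and the highest was 33 (two-sided permutation p = 0.0002, the smallest that 10000 shifts can give). Among the thresholded peaks, 1152 had a summit in the top 1631 of both replicates, and 37 had one in neither. Across 1626 thresholded peaks with an entry in both replicates, the signal values had a Spearman rho of 0.754 (bootstrap 95% interval 0.726 to 0.779). That value is across peaks, which are not independent replicates, and 5 peaks had no entry in one of the replicates. It takes the strongest overlapping entry of each replicate, which neighbouring peaks can share. With the overlapping entry of nearest summit instead, rho was 0.712, below that interval.

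**Figure D1:**
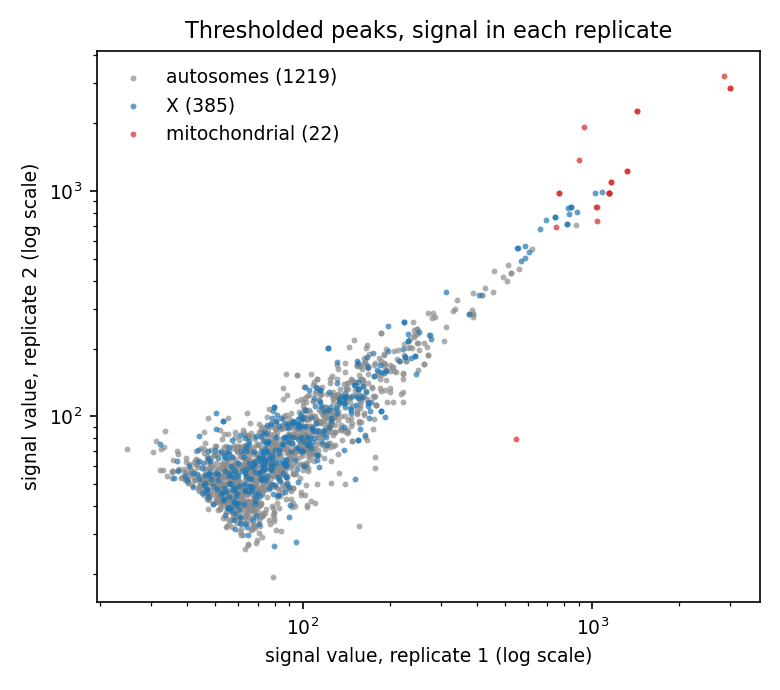
Signal value of each thresholded peak in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, with 1 point per peak and colours for autosomal, X and mitochondrial peaks. The rank correlation was 0.754 with the strongest overlapping entry of each replicate, and the 22 mitochondrial peaks include the highest values in both replicates.

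The region around tbx-2 held a cluster of peaks, most of them outside the gene. The gene lies on the minus strand at III 5130923 to 5136296. A thresholded peak at 5136268 to 5136518, with its summit 109 bp upstream of the transcript start, had a signal value of 332 in the pooled list, 194 in replicate 1 and 146 in replicate 2. In all, 14 thresholded summits lay within 15000 bp of the gene, from position 5125952 to 5144377, against a median of 0 for protein-coding genes. Of these 14, 9 were in the top 1631 of both replicates, and the strongest had a signal value of 371. The strain carries a tagged tbx-2 transgene beside the endogenous gene, and extra copies of the region from it may add to this cluster.

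**Figure D2:**
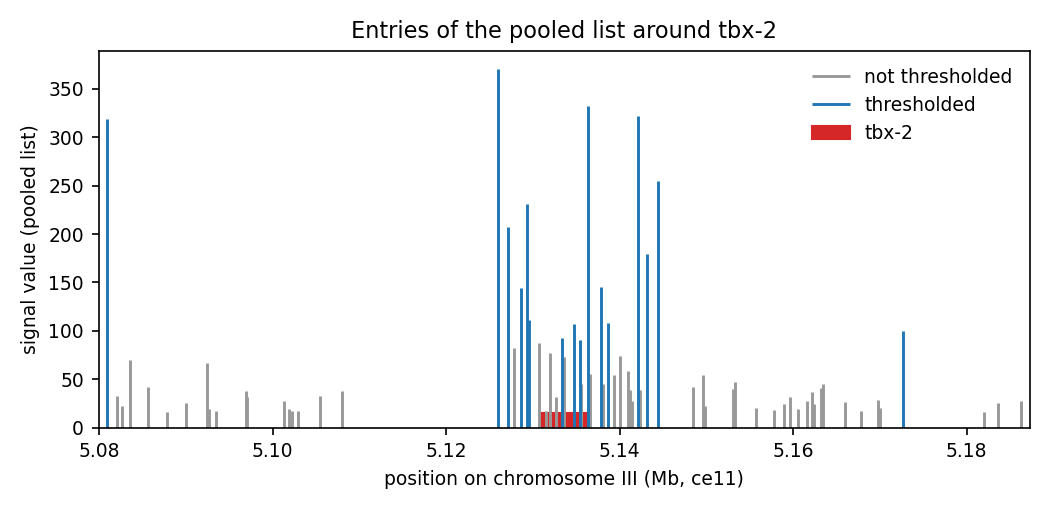
Entries of the pooled ranked list around tbx-2 on chromosome III, with position on build ce11 in Mb on the x axis and the authors' signal value on the y axis. Each line is the summit of 1 entry, the bar marks tbx-2, and 14 thresholded summits fall between 5125952 and 5144377.

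Genes linked to TBX-2 or to pharyngeal muscle in earlier work were mostly without a thresholded peak. On ce11, no thresholded summit lay in, or within 5000 bp of, pha-4, the FoxA regulator of pharyngeal identity, or ceh-22, an NK-2 homeobox regulator of pharyngeal muscle. The same held for myo-2, a myosin heavy chain of pharyngeal muscle, for ubc-9, the SUMO-conjugating enzyme, and for D2096.6. The strongest promoter entry of ubc-9, at IV 4650585 to 4651004, ranked 1658 in the pooled list with a signal value of 90.1. The lowest thresholded value on ce11 was 91.0. This ubc-9 entry ranked 1148 in replicate 1 and 3634 in replicate 2. The authors' thresholded list on ce10 reached down to a signal value of 73.02, so an entry of this strength may be thresholded there. Whether that list holds a peak at ubc-9 was not checked. The strongest promoter entries of pha-4, ceh-22 and D2096.6 ranked 4588, 6309 and 14918 of 30000, and myo-2 had no entry in its promoter window. Of all 19985 protein-coding genes, 5.41% had a thresholded summit in that window, so a gene without one is the common case. Only whole L3 worms were measured, so binding at other stages or in a small share of cells may be missed. The missing peaks thus do not show that TBX-2 leaves these genes unbound.

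Thresholded peaks gathered at promoters and, outside promoter windows, were rare in coding exons. The summit of 880 of 1631 peaks, 53.95% (exact 95% interval 51.5 to 56.4%), lay in the promoter window of a protein-coding gene. This compared with 29.9% of the 27922 pooled entries that no thresholded peak overlapped (odds ratio 2.75, two-sided Fisher's exact p = 1.77e-85) and with 26.6% of 10000 random positions (Fisher's exact p = 4.92e-102). With the starts of all annotated genes, 74.7% of thresholded summits and 41.7% of unthresholded entries lay in such windows. Of the nuclear summits outside coding promoter windows, 425 were intergenic, 273 intronic, 38 in coding exons and 12 in untranslated exons. These classes use protein-coding genes alone, so intergenic summits can lie at RNA genes. Coding exons outside promoter windows thus held 2.33% of thresholded summits, against 19.6% of the unthresholded entries. Summits in coding exons inside promoter windows were not counted apart. The median distance to the nearest coding transcript start was 616 bp for thresholded summits and 1176 bp for unthresholded ones, and 71.9% of thresholded summits were upstream of that start. The tests treat summits as independent, although neighbouring summits can share a fragment.

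Mitochondrial genes and ribosomal protein genes were among the genes with the strongest summits in their promoter windows. Of the 25 protein-coding genes with the strongest promoter summits found in both replicates, 9 were mitochondrial (CYTB, ND4, COX1, ATP6, COX2, ND1, ND2, ND3 and ND5). The other 16 were nuclear and shared 12 distinct summits, all upstream of the transcript start. Of these, 4 encode proteins of the large ribosomal subunit: rpl-3 with a signal value of 1583, rpl-20 with 1172, rpl-15 with 1008 and rpl-35 with 811. The peak at II 10563403 to 10563747, with a signal value of 907, lay 170 bp upstream of cdc-48.1, which encodes an AAA ATPase of protein quality control. The peak at I 4171940 to 4172689, with a signal value of 906, lay 699 bp upstream of egg-5, which acts at the oocyte-to-embryo transition. The peak at III 12905044 to 12905354, with a signal value of 741, lay 291 bp upstream of cox-5A, a subunit gene of cytochrome c oxidase. On X, ins-39, an insulin-like peptide gene, had a peak of 1101 and nspc-17 had one of 1695. Their summits lay 648 and 723 bp upstream, and both held the 12-base sequence taken further below as the MEX site. The remaining 7 genes were Y17G9B.5, K11H12.8, K01G5.10, tasp-1, nhl-2, tag-340 and H41C03.3, with signal values from 762 to 1172. The mitochondrial genome is 13794 bp long, so the promoter windows of its genes overlap and span much of it. A mitochondrial summit in such a window thus does not single out a gene, and the same peak counted for both ND3 and ND5.

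The lists of ribosomal protein genes, heat shock and stress genes and heterochronic genes carried thresholded promoter peaks more often than other genes, and chemoreceptor genes less often. Of 19985 protein-coding genes, 1081 (5.41%) had a thresholded summit in their promoter window. Among 78 cytoplasmic ribosomal protein genes, 44 did, which is 56.4% (exact 95% interval 44.7 to 67.6%), with an odds ratio of 23.5 (Fisher's exact test, adjusted p = 4.39e-34). These were 26 of 47 rpl genes of the large subunit and 18 of 31 rps genes of the small subunit. In the list of heat shock and stress genes, 7 of 17 members had a peak (odds ratio 12.3, Fisher's exact adjusted p = 0.000123), and 5 of 17 did without replicate 1 (odds ratio 7.74, Fisher's exact adjusted p = 0.00994). The strongest were those of hsp-60, a mitochondrial chaperonin, with a signal value of 565, hsp-90 with 481, hsp-1, a cytosolic HSP70, with 404 and hsp-3, an HSP70 of the endoplasmic reticulum, with 276. The others were hsp-110, hsp-6 and the transcription factor gene daf-16, while all 6 genes of the heat-inducible hsp-16 family, hsp-70, hsp-4, hsf-1 and skn-1 had none. In the heterochronic list, whose genes set the timing of larval development, 6 of 13 members had a peak (odds ratio 14.995, Fisher's exact adjusted p = 0.000180), and 4 of 13 did without replicate 1 (odds ratio 8.20, Fisher's exact adjusted p = 0.0199). The strongest of these were at mir-241 with 298, lin-28 with 201, lin-4 with 167 and lin-14 with 135. The list also passed without let-7, 1 of the 6 (5 of 12 genes, odds ratio 12.5, Fisher's exact adjusted p = 0.00154), and with a window of 500 bp upstream (Fisher's exact adjusted p = 0.00884). With both changes together it did not (3 of 12 genes, odds ratio 7.76, Fisher's exact adjusted p = 0.0671). Of 413 chemoreceptor genes of the srh and str families, 2 had a peak, srh-16 with 292 and srh-2 with 174 (odds ratio 0.0834, Fisher's exact adjusted p = 6.73e-07), and 3 did without replicate 2 (odds ratio 0.130, Fisher's exact adjusted p = 1.05e-05). All p-values of the lists are two-sided and adjusted by the Benjamini-Hochberg method over the 23 lists, without microRNAs in the autosomal and free-upstream settings. Because 249 summits lay in the promoter windows of several coding genes, members of a list can share a summit.

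The other lists did not pass the threshold. None of the 12 pharyngeal muscle genes had a peak (exact 95% upper bound 26.5%, Fisher's exact adjusted p = 1), and of 14 pharyngeal regulators only tbx-2 did (adjusted p = 0.911 in the same exact test). Of 21 T-box factor genes, tbx-2 was again the only one. Extra copies of the tbx-2 region from the tagged transgene may add to its entries. The peak therefore does not by itself show binding of TBX-2 at its own gene. The pan-neuronal list had peaks at 4 of 17 genes, maco-1 with a signal value of 200.2, rab-3 with 129, rgef-1 with 116 and egl-21 with 102 (odds ratio 5.40, Fisher's exact p = 0.0115, adjusted p = 0.0529). That list passed the threshold with each replicate alone (Fisher's exact adjusted p = 0.0474 for replicate 1 and 0.0440 for replicate 2), with a window of 2000 bp upstream (6 of 17, Fisher's exact adjusted p = 0.00418) and with autosomal peaks and genes only (4 of 14, Fisher's exact adjusted p = 0.0210). It also passed with each summit given to its nearest transcript start at any distance (9 of 17, Fisher's exact adjusted p = 2.21e-06). It did not pass with a window of 500 bp upstream (2 of 17, Fisher's exact adjusted p = 0.504), among the strongest 815 peaks (1 of 17, Fisher's exact adjusted p = 0.841) or among genes with 1000 bp free upstream (3 of 15, Fisher's exact adjusted p = 0.0918). No promoter peak was found at the 19 epidermal, 11 seam cell or 23 intestinal genes. With each summit given to its nearest transcript start at any distance, 5 of the 19 epidermal genes had one (Fisher's exact adjusted p = 0.0267), and without replicate 1 a single one did. Single peaks were found at uba-2 among 9 SUMO pathway genes, act-4 among 18 body wall muscle genes and egl-4 among 15 chemosensory neuron genes. Single peaks were also found at cgh-1 among 18 germline genes and egl-17 among 14 genes of vulval development. Histone genes had peaks at 8 of 72 members, led by his-37 with 669, and shared summits such as that between his-67 and his-68, with 284 (odds ratio 2.19, Fisher's exact adjusted p = 0.191). Of the 5 histone genes with 1000 bp free upstream, 3 had a peak, and the list passed in that setting alone (odds ratio 33.3, Fisher's exact adjusted p = 0.00403). The vacuolar ATPase list had 3 of 20, at vha-8, vha-12 and vha-13, and the collagen list had 3 of 156, at col-185, col-38 and col-71. Peaks lay at 2 of 63 homeobox genes of the ceh series (ceh-38 and ceh-20), 2 of 25 bHLH genes (hlh-11 and hlh-30) and 12 of 269 nuclear receptor genes, with nhr-47, nhr-68, nhr-142 and nhr-1 the strongest. Among 260 microRNA genes 19 had a peak, led by the mir-54, mir-55 and mir-56 cluster with 394 and mir-354 with 337. The microRNA test holds no information, because only 1 other gene of that biotype was annotated.

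**Figure D3:**
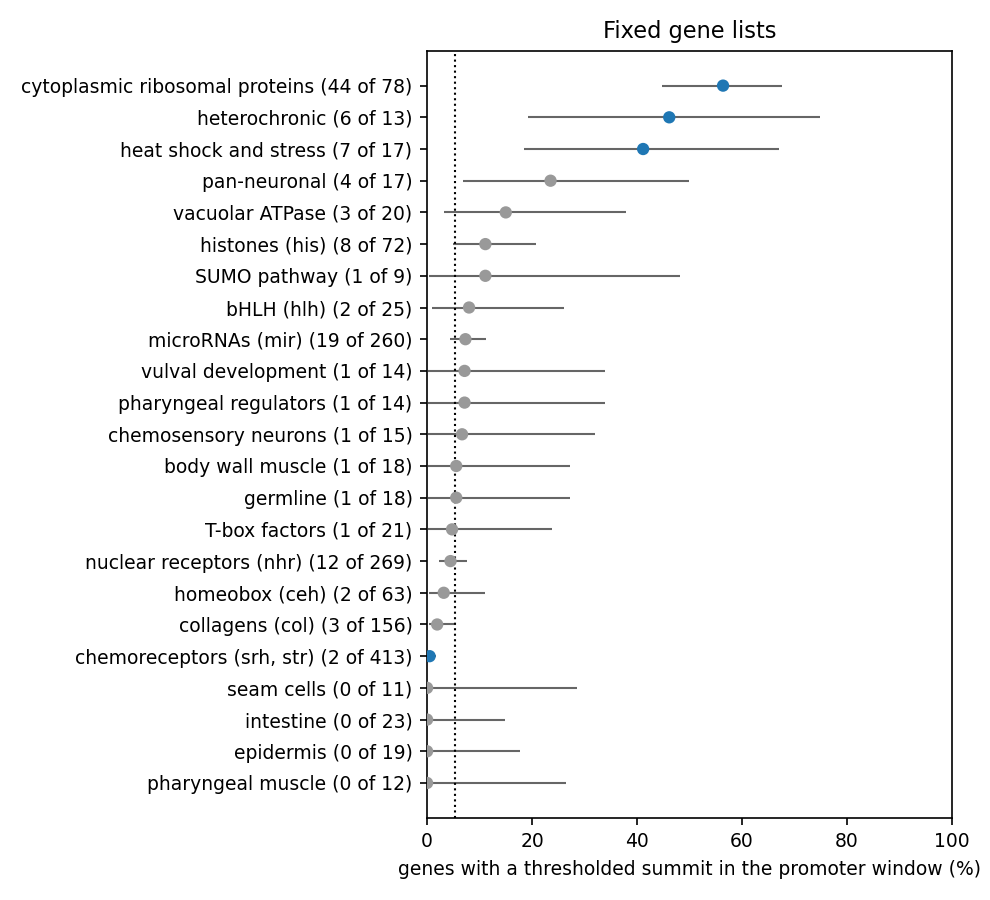
Share of genes in each fixed list with a thresholded summit in the promoter window (x axis, percent), with exact 95% intervals as lines and the number of members in brackets. Coloured points passed the threshold of 0.05 after adjustment, and the dotted line marks the 5.41% of all protein-coding genes.

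Thresholded summits lay more often on X, and more often in the central part of autosomes, than length alone would give. On X lay 386 of 1609 nuclear summits, 24.0% (exact 95% interval 21.9 to 26.2%), against 17.7% of nuclear genome length (two-sided exact binomial p = 1.65e-10). The share was 44.0% among the strongest 50 nuclear peaks and 17.9% among the unthresholded pooled entries. Chromosome X held 21.8 peaks per Mb, chromosome III held 19.3 and chromosome V held 11.1, the lowest of the 6. The central 50% of the chromosomes held 961 nuclear summits, 59.7% (exact binomial p = 6.07e-15), and 53.4% of the unthresholded entries (exact binomial p = 9.01e-30). On autosomes this share was 63.5% and on X it was 47.9% (Fisher's exact p = 7.80e-08 for the difference, a test added after the data were seen). Leaving out peaks within 200 bp of tRNA genes, a setting chosen after the data were seen, gave an X share of 20.8% (exact binomial p = 0.00183). Among the 861 nuclear summits in promoter windows, also set apart after the data were seen, the X share was 19.98% and did not pass the threshold (exact binomial p = 0.0813), while among the other 748 it was 28.6% (exact binomial p = 1.95e-13).

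**Figure D4:**
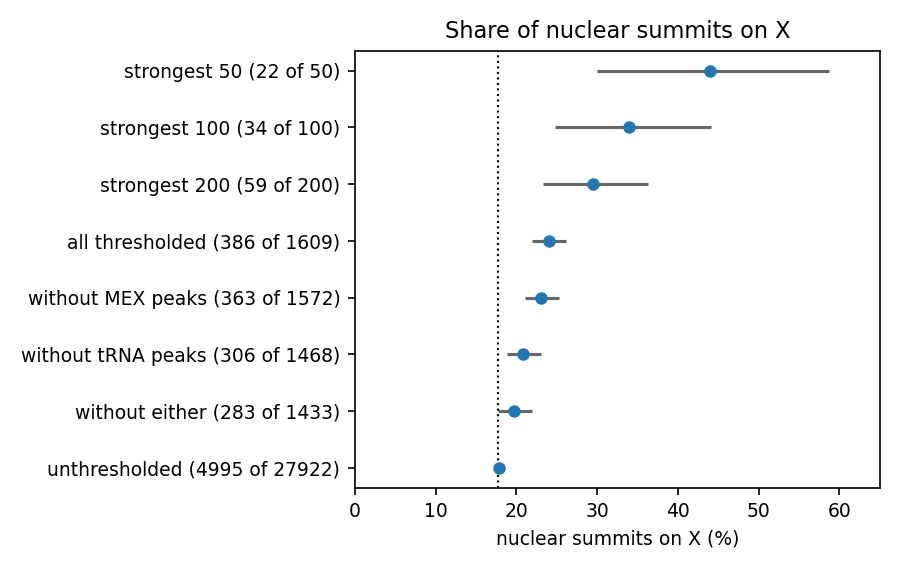
Share of nuclear summits on X (x axis, percent) for sets of peaks given on the y axis with their numbers, with exact 95% intervals as lines; MEX peaks hold a 12-base sequence taken as the MEX site and tRNA peaks lie within 200 bp of a tRNA gene. The dotted line marks the 17.7% of nuclear genome length on X, and the share falls from 44.0% in the strongest 50 peaks to 17.9% in the unthresholded entries.

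The sequence GGTGTGA, bound by T-box factors, was no more frequent at the summits than beside them. Within 100 bp of the summit it was found in 16 of 1631 peaks, 0.981% (exact 95% interval 0.562 to 1.59%), against 42 of 3262 windows centred 1000 bp to either side, 1.29% (odds ratio 0.760, two-sided Fisher's exact p = 0.402, adjusted p = 0.482 over 12 sites). The shorter core GGTGTG was found in 7.48% of summit windows and 4.97% of flank windows (Fisher's exact adjusted p = 0.00113). The longer AGGTGTGA was found in 0.245% and 0.215%, a difference that did not pass the threshold. Summit windows had a mean GC content of 45.4% against 36.6% in the flanks. Against windows matched on GC content, GGTGTGA was less frequent at summits (1.90% in the matched windows, Fisher's exact adjusted p = 0.0304), and the core did not differ beyond the threshold (6.56%, Fisher's exact adjusted p = 0.277). The longer AGGTGTGA, in 0.644% of the matched windows, did not differ beyond the threshold either (Fisher's exact adjusted p = 0.149).

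Other sequence sites were enriched at the summits. The GAGA repeat GAGAGAG was found in 21.9% of summit windows, 3.43% of flank windows and 5.18% of GC-matched windows (odds ratio 7.91 against flanks, Fisher's exact adjusted p = 1.52e-88). The GC-rich site GGGCGG was found in 10.97%, 3.31% and 6.59% of these windows (Fisher's exact adjusted p = 2.83e-24 against flanks). The FoxA site TGTTTRC was found in 9.69%, 5.40% and 4.57% (Fisher's exact adjusted p = 1.21e-07 against flanks). The bZIP site TGACGTCA was found in 1.66% of summit and 0.889% of flank windows (Fisher's exact adjusted p = 0.0377), and that difference did not pass against GC-matched windows (Fisher's exact adjusted p = 0.154). The GATA site TGATAA and the site RTCAT were less frequent at summits than in flanks, with 10.2% against 18.8% and 45.2% against 54.7% (Fisher's exact adjusted p = 6.76e-15 and 1.75e-09). The GATA difference was absent against GC-matched windows, of which 10.6% held the site (Fisher's exact adjusted p = 0.656). The NK-2 site, the E-box and TTAGGC did not differ from the flanks beyond the threshold, with 3.19%, 9.44% and 4.41% of summit windows holding them, although the E-box was less frequent than in GC-matched windows (13.7%, Fisher's exact adjusted p = 4.11e-05).

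**Figure D5:**
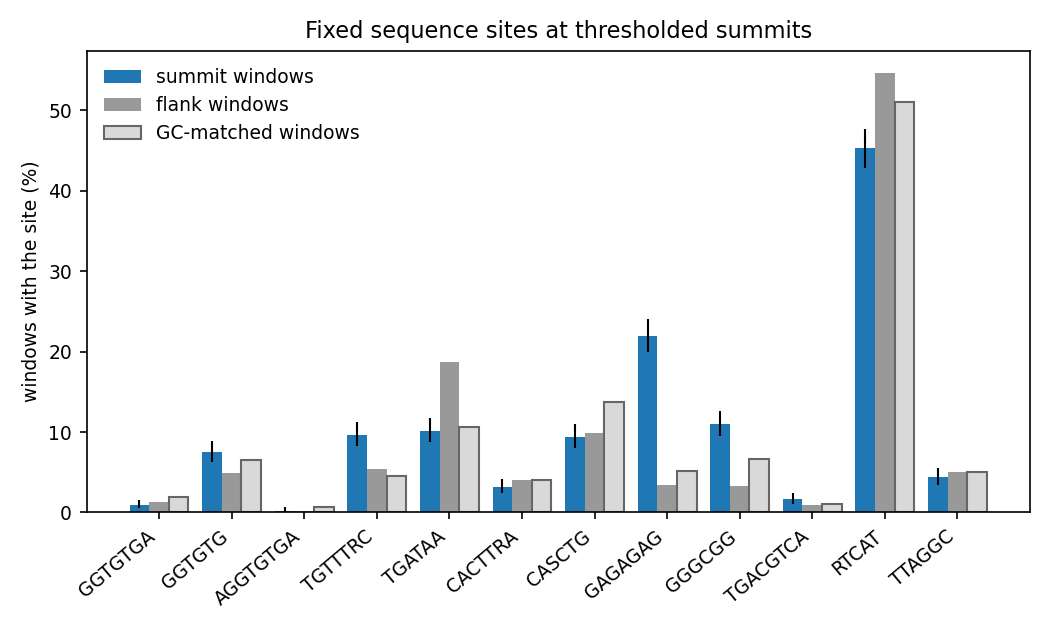
Share of windows that hold each fixed sequence site (y axis, percent) in summit windows, windows 1000 bp to either side and random windows matched on GC content, with exact 95% intervals on the summit bars. GAGAGAG differs most, with 21.9% of summit windows against 3.43% of flank windows, while GGTGTGA is at 0.981% against 1.29%.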

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

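The thresholded list on build ce10, which entered none of the main comparisons, held 712 more peaks than the list on ce11, 2343 against 1631. The pooled list on ce11 also held 2343 entries at or above the lowest thresholded signal value on ce10, which was 73.02. The ranked list of replicate 1 differed in length between the builds, with 28366 entries on ce11 and 29095 on ce10, while those of replicate 2 and of the pool had 30000 on both. No test of the difference was made, and its origin was not examined.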

How the results depend on the processing

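Settings without mitochondrial entries, by peak location, by distance from tRNA genes, without peaks that hold the X-linked site, on autosomes alone, without let-7 and for the core T-box sequence with matched or shuffled controls were chosen after the data were seen. The replicate overlap, the promoter share and the share in the central 50% of chromosomes kept their direction and their side of the threshold under every alternative run for them, and so did the share of X except among promoter peaks, where it was 19.98% (exact binomial p = 0.0813) and the cause was not tested. The rank correlation moved beyond its interval to 0.712 with the nearest entry and 0.722 on ce10, and the cause was not tested. The share of GGTGTGA, 0.981%, passed the threshold as a depletion against the unthresholded entries (1.65%, Fisher's exact p = 0.0336), dinucleotide-shuffled windows (2.36%, Fisher's exact p = 0.000762) and GC-matched windows (1.90%, Fisher's exact p = 0.0152). The direction reversed for the core sequence, found in 7.48% of summit windows, against flanks (4.97%), GC-matched windows (6.56%, Fisher's exact p = 0.231) and shuffled windows (7.42%, Fisher's exact p = 0.954). For AGGTGTGA the direction reversed against flanks, with 4 of 1631 summit windows (0.245%) against 7 of 3262 (0.215%), which did not pass the threshold. It did not reverse against GC-matched windows, with 0.644% (Fisher's exact p = 0.0869). Beyond these controls, the cause of the reversals was not tested. Under all 8 alternatives that could change them, the ribosomal protein, heat shock and chemoreceptor lists passed in the same direction, with highest Fisher's exact adjusted p-values of 0.00202, 0.0191 and 0.00474. The heterochronic list, which holds let-7, passed in 9 of 10, and did not with the window of 500 bp upstream when let-7 was left out as well (3 of 12 genes, Fisher's exact adjusted p = 0.0671). The pan-neuronal list passed in 5 of 8. The histone list passed in 1 of 8, among genes with free upstream sequence (3 of 5 genes, Fisher's exact adjusted p = 0.00403). The epidermal list reversed from 0% to 26.3% when each summit went to its nearest transcript start only (Fisher's exact adjusted p = 0.0267), a setting with no limit on distance. Of 67 named genes with a promoter peak, 20 lost it with the window of 500 bp upstream, 16 of them because no entry was left in the window, while 3 lost it without replicate 1 and 2 without replicate 2. The lists give no read depth, so its effect could not be examined.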

Other observations

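Tests of RNA gene classes, of short sequences, of mitochondrial coverage, of the share of X among unthresholded entries and of the X share without particular peaks were chosen only after the results were seen.

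Thresholded summits gathered at genes for small structural RNAs. Of 1609 nuclear summits, 141 (8.76%) lay within 200 bp of a tRNA gene, against 1.03% of the unthresholded entries (odds ratio 9.22, two-sided Fisher's exact adjusted p = 1.82e-70 over 7 classes). Summits near snoRNA genes made up 4.66% against 0.398% (Fisher's exact adjusted p = 5.52e-45), and those near snRNA genes 1.62% against 0.107% (Fisher's exact adjusted p = 3.63e-18). MicroRNA genes had 0.622% against 0.240% (Fisher's exact adjusted p = 0.0155), and piRNA genes had fewer, 0.746% against 1.45% (Fisher's exact adjusted p = 0.0230). For lincRNA genes the shares were 0.622% and 0.383% (Fisher's exact adjusted p = 0.173). No thresholded summit lay near any of the 20 nuclear rRNA genes. Only 1 of 27922 unthresholded entries did, so that absence says little. Of 612 nuclear tRNA genes, 276 are on X, as were 80 of the 141 peaks.

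Among 8192 sequences of 7 bases, GAGACGC was found in 18.3% of summit windows on autosomes against 1.59% of flank windows (Fisher's exact adjusted p = 3.68e-69) and on X in 11.4% against 1.30% (Fisher's exact adjusted p = 5.21e-11). In all, 1386 of these sequences passed as more frequent at autosomal summits and 1085 as less frequent. The counts on X were 727 and 438, so passing was common. The flanks, whose GC content was lower, were the only control for these sequences. On X, GAGAGAG was found in 20.5% of summit windows against 3.50% (Fisher's exact adjusted p = 4.01e-16), GAGAGGG in 13.2% against 1.04% (Fisher's exact adjusted p = 1.20e-14) and GGTTCGA, part of the internal promoter of tRNA genes, in 14.0% against 1.42% (Fisher's exact adjusted p = 3.78e-14). The sequence GAGAGAG was found in 24 of the 200 strongest entries of the pooled list (exact 95% interval 7.84 to 17.3%), in 30.5% of those ranked 201 to 400 (24.2 to 37.4%) and in 3.96% of those ranked 20001 to 30000.

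Nuclear summits lay on X in 24.0% of cases, more than the 17.7% of genome length. Against an excess at every signal level stood a share of 17.9% in unthresholded entries (Fisher's exact p = 2.53e-09 for the difference), and against a single replicate stood a lower bound of 21.9% in the replicate where it was lower. The sequence TCGCGCAGGGAG, taken as the MEX site through which the dosage compensation machinery is recruited to X but not checked against a published motif, was found with up to 2 mismatches in 23 of 386 X summit windows and 14 of 1223 autosomal ones, a difference of 4.81 percentage points (Fisher's exact p = 6.29e-07), and in 14 of the 22 X peaks among the strongest 50 nuclear peaks, so recruitment sites of that machinery may be among the strongest X peaks if the sequence is right. Peaks with this sequence did not account for the whole excess, since the X share without them was 23.1% with a lower bound of 21.03%, and without them and the peaks near tRNA genes it was 19.7% (exact binomial p = 0.0410), but recruitment sites without it were not removed, and 8 of those 22 X peaks lacked it. Whether TBX-2 itself or signal that recurs in immunoprecipitations of other proteins lies at these sites stays open, because no other immunoprecipitation was analysed here.

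Entries were dense around tbx-2, with 32 pooled entries within 15000 bp of the gene against a 95th percentile of 22 among 19973 nuclear protein-coding genes. For thresholded peaks, 14 lay there, and 3 genes, tbx-2 included, had as many or more. Extra copies of this region carried by the tagged transgene may add to these 32 entries, a count above the percentile having been set as the sign of that before the data were examined. Binding of TBX-2 at its own gene was not tested and stays open.

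All 22 mitochondrial entries of the pooled list were thresholded, and together they covered 64.4% of the mitochondrial genome. Because this coverage was known when it was set as a test, it does not decide whether the high copy number of mitochondrial DNA gave rise to these entries, and that stays open. None of the 22 summit windows held GGTGTGA, and no biological explanation was tested.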
